A study of Mus musculus with 25 samples.

How the data were processed

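RNA was measured by Smart-seq2, a method that amplifies full-length cDNA from very small inputs, in mouse oocytes and early embryos of strain C57BL/6. Per the labels, immature oocytes were matured in culture for 16 h to metaphase II (MII), the stage at which an oocyte waits for the sperm, and embryos came from in vitro fertilization lasting 6 h. The culture media held either PBS, a buffered salt solution used as the control, or a small molecule written as VCD. The full name of VCD and its dose are not given in the sources used here. The 25 libraries fell into 6 groups: MII oocytes with PBS (n = 4) and VCD (n = 5), 2-cell embryos with PBS (n = 4) and VCD (n = 4), and morulae, embryos before the blastocyst cavity forms, with PBS (n = 4) and VCD (n = 4). The number of oocytes or embryos in each library, and whether the libraries of a group came from separate animals or cultures, are not given either, so the p-values measure only the spread between these samples.

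Per the submitters' processing notes, Bowtie2 2.2.3 and TopHat2 2.0.12 were used, and the genome build is given as the chicken build galGal4. All gene identifiers in the deposited tables were mouse Ensembl identifiers, so that build entry could not be the source of the gene table, and no coordinates were taken from it. The counting tool and the annotation are not stated. The authors deposited FPKM (fragments counted per gene, divided by transcript length and by the library total) in 2 tables, 1 for oocytes with 25158 genes and 1 for embryos with 34228 genes. Gene symbols were matched by identifier for 25073 and 34065 of them. FPKM corrects for library size and gene length but not for a few very abundant genes, so a change in those genes shifts all others.

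Read counts were not used here, since both tables held FPKM. The depth was worked out from the values: FPKM times the summed exon length of each gene in GENCODE M21 fell on whole multiples of 1 step per library, and between 90.6% and 93.4% of the values corresponding to fewer than 200 reads were whole within 0.01. The step implied between 15075832 and 20998296 counted reads or fragments per library; whether these were reads or pairs is not stated. At this depth 1 read in a gene of 1 kb corresponded to between 0.0476 and 0.0663 FPKM. These recovered reads were used only for depth, for a few short genes and for alternatives. Amplified cDNA without molecular identifiers does not give independent molecules, so any interval or test on reads covers counting error only.

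The design for counts needed whole counts, so the design written beside it for normalized values was used: limma 3.58.1 in R 4.3.3, with a trend of the variance on abundance, on log2(FPKM + 1), with genes at 1 FPKM or more in at least 4 libraries of the comparison. Fold changes are on that scale, which understates changes of genes of low abundance. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. VCD was compared with PBS within each stage, the VCD effect in morulae with that in 2-cell embryos as an interaction, and PBS morulae with PBS 2-cell embryos. Gene symbols are followed by log2 fold change and standard error (SE), and FPKM by standard deviation (SD).

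The comparisons, 32 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Array weights, limma-voom and a filter on recovered reads, and leaving out libraries on the genes of the full set were added later. The rule took the genes of largest change with adjusted p below 0.05, groups that did not overlap and a mean of 5 FPKM or more in the higher group, and, where fewer than 10 qualified, the 10 genes of smallest unadjusted p. It added the 2 members of smallest p of each list and a fixed panel of 11 genes. Lists with 5 or more tested members were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, then with an estimated correlation, and with fry, which tests only whether a list moves 1 way on balance. Among the lists were markers of cells that an oocyte or embryo sample could carry along, such as cumulus and granulosa cells.

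Depth, detected genes, mitochondrial share, share of the 10 most abundant genes and Y-linked expression were compared between agents by two-sided exact permutation tests, adjusted over 15 tests. Whole profiles were compared by an exact permutation test of the ratio of distances between and within agents, with 1 minus Pearson's r as the distance. For the named genes, the share of 50-base words of their annotated transcripts that also occurs in transcripts of another annotated gene was counted. This check was added after the results were seen. Coordinates are those of GRCm38 with the GENCODE M21 annotation.

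The tests were run first on simulated data with 200 changed genes. The shares are of the changed genes that passed the filter on low values. A 4-fold change was recovered for 100% of 95 such genes in oocytes (8268 genes run) and 96.8% of 93 in 2-cell embryos (10340 genes). It was recovered for 91.8% of 98 in morulae (9177 genes) and 77% of 100 for the interaction (12863 genes). A 2-fold change was recovered for 86.6%, 65.3%, 53.1% and 26% in the same order. For morulae against 2-cell embryos (9863 genes) these shares were 95.4% and 78.0%. The simulated spread was the same for both groups and independent between genes, and 200 changed genes loosen the adjustment. The shares may therefore be higher than in the data.

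Alternatives were other filters on low values, another pseudocount, rescaling by the median of ratios, the number of detected genes as a covariate, replicate numbers as a block, 1 fit of all 16 embryo libraries, leaving out each library in turn, array weights, and limma-voom on the recovered reads. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the other steps. No library was left out.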

Results

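Smart-seq2 libraries of mouse MII oocytes, 2-cell embryos and morulae exposed in culture to PBS or VCD were compared within each stage. Each group held 4 libraries, except MII oocytes with VCD, which held 5. The steps of the FPKM values implied between 16382925 and 20055010 counted reads or fragments per library in oocytes, between 15075832 and 20787456 in 2-cell embryos, and between 15304093 and 20998296 in morulae.

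As whole profiles, the libraries with VCD and with PBS did not part by more than their spread in any stage. Pearson's r across genes lay between 0.975 and 0.991 for oocyte libraries of the same agent and between 0.980 and 0.990 for libraries of different agents. These ranges were 0.9505 to 0.979 and 0.959 to 0.978 in 2-cell embryos, and 0.925 to 0.973 and 0.940 to 0.967 in morulae. The exact permutation tests, which count only ratios as large as the real one or larger, gave p = 0.944, 0.857 and 0.8286 for the 3 stages. The smallest possible values were 0.00794, 0.0286 and 0.0286. Genes at 1 FPKM or more numbered 8527 ± 112 (SD, n = 4) with PBS and 8591 ± 277 (n = 5) with VCD in oocytes, 11354 ± 203 and 11371 ± 423 (n = 4 each) in 2-cell embryos, and 9917 ± 62.0 and 9954 ± 324 (n = 4 each) in morulae. The mitochondrially encoded genes held 1.82% ± 0.272 and 2.03% ± 0.565 of all FPKM in oocytes with PBS and VCD, 6.10% ± 0.426 and 5.26% ± 1.16 in 2-cell embryos, and 6.77% ± 0.674 and 7.12% ± 1.07 in morulae. None of the 15 exact permutation tests of library measures passed after adjustment (smallest adjusted p = 0.824). The smallest unadjusted value was that of the implied depth in morulae (exact p = 0.0571).

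The mean distance of a library to the others of its own group, as 1 minus r, was 0.0101 with PBS and 0.0196 with VCD in oocytes. It was 0.0251 and 0.0358 in 2-cell embryos, and 0.0419 and 0.0545 in morulae.

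**Figure D1:**
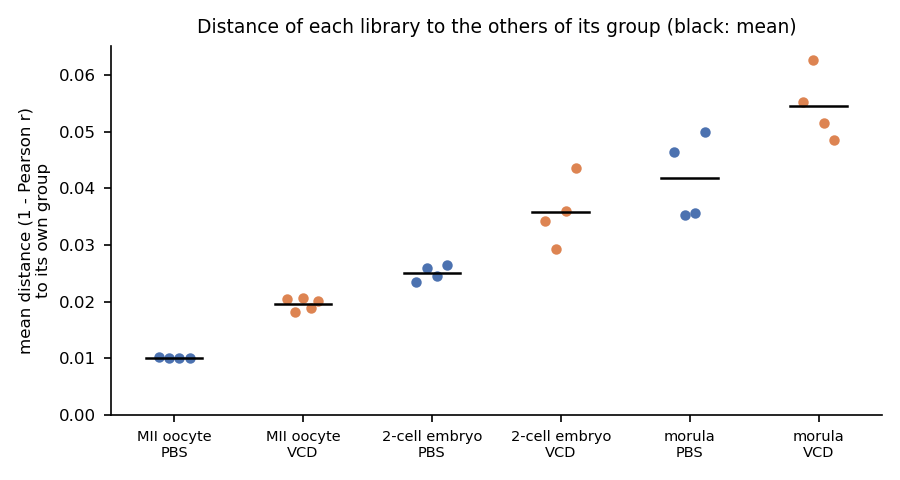
Mean distance (1 minus Pearson's r across tested genes) of each library to the other libraries of its own group, by stage and agent; each point is a library and the black line is the group mean. Group means were 0.0101 (PBS) and 0.0196 (VCD) in oocytes, 0.0251 and 0.0358 in 2-cell embryos, and 0.0419 and 0.0545 in morulae.

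The first comparison asked which transcripts differed in MII oocytes matured with VCD. Gm24984, annotated as a small nucleolar RNA of unnamed function, rose with VCD by 1.36 on the log2 scale (SE 0.13, adjusted p = 0.00444), from 0.200 ± 0.230 FPKM (SD, n = 4) to 2.04 ± 0.229 (n = 5), with no overlap between the groups. None of the fixed panel passed (adjusted p = 0.999). Gdf9, a growth factor secreted by the oocyte, had 3363 ± 204 and 3281 ± 191 FPKM, and Zp3, a protein of the egg coat, 677 ± 216 and 734 ± 373. Mos, the kinase that holds the MII arrest, had 256 ± 17.4 and 257 ± 84.9 FPKM. Dppa3, a maternal protein that protects DNA methylation after fertilization, had 76.3 ± 7.55 and 98.4 ± 60.2. Hspa5, a chaperone of the endoplasmic reticulum, had 45.6 ± 4.79 and 47.8 ± 19.4 FPKM, the mitochondrial superoxide dismutase Sod2 10.3 ± 0.483 and 9.80 ± 1.44, and the pluripotency factor Pou5f1 5.43 ± 1.45 and 6.69 ± 2.87. Nanog, Cdx2, Zscan4d and Cdkn1a were too low to be tested.

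Gm24984 (ENSMUSG00000077642) lies on chromosome 10 from 72527550 to 72527682, overlaps no other gene listed in the deposited tables and is 133 bases long. Its values corresponded to 2 reads over all PBS libraries and 25 over all VCD libraries, with 4 to 6 in each of the latter. In 2-cell embryos Gm24984 ranged from 0 to 1.91 FPKM among PBS libraries and from 0 to 2.17 among VCD libraries. The genes next in order of unadjusted p did not pass (adjusted p = 0.999). Among them, Smox, which oxidizes the polyamine spermine, had 1.24 ± 0.208 FPKM with PBS and 2.27 ± 0.375 with VCD (log2 fold change 0.55, SE 0.11). Cdt1, which licenses replication origins, had 34.9 ± 3.45 and 45.4 ± 4.49 FPKM (0.37, SE 0.10), and Wdtc1 10.6 ± 0.749 and 14.6 ± 2.10 (0.43, SE 0.11). Zfp933, a zinc finger protein, had 4.32 ± 0.183 and 3.04 ± 0.226 FPKM (−0.40, SE 0.09), Trim35 2.32 ± 0.294 and 3.38 ± 0.277 (0.40, SE 0.10), and Rnf207 1.201 ± 0.178 and 1.86 ± 0.268 (0.38, SE 0.10). Gm48940 (−0.49, SE 0.13), Gm42439 (−0.58, SE 0.15) and Rab11b-ps2 (0.39, SE 0.11) completed the 10; Rab11b-ps2 and Gm48940 share 91.7% and 31.3% of their 50-base words with another gene, so their values are uncertain. Of 8715 genes tested with limma, 1 was higher and 0 were lower, 245 had an unadjusted p below 0.05 where 435.75 would by chance, and voom, which did not test Gm24984, called 0, with 371 below 0.05. A mean of 5 FPKM or more in the higher group was found for 4744 genes. Of these, 4716 (99.4%) had a 95% confidence interval within a 2-fold change. The call of Gm24984 was lost without a filter on low values (adjusted p = 0.0635) and with a pseudocount of 0.1 (adjusted p = 0.394), within a range of 0.00230 to 0.394 over its alternatives.

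Of 28 gene lists in oocytes, DNA and histone modification passed: 28 of its 33 tested members had positive and 5 negative values, with a median of 0.12 (adjusted p = 0.0182; adjusted p = 0.989 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Kat5, a histone acetyltransferase, had 2.19 ± 0.704 FPKM with PBS and 3.02 ± 0.478 with VCD, and Setdb1, a histone H3 lysine methyltransferase, 10.9 ± 1.26 and 13.7 ± 2.63. In the other lists, the glycolysis enzymes had the smallest adjusted p (0.276), with 9 of 11 members positive. In 11 lists the median, the mean and the test differed in sign, DNA and histone modification not among them. That list lost its call without PBS replicate 3 (adjusted p = 0.0703), PBS replicate 4 (0.112), VCD replicate 2 (0.132) or VCD replicate 4 (0.262), with a range of 0.00321 to 0.996 over its alternatives. On the genes of the full set it also lost the call without PBS replicate 1 (adjusted p = 0.0502).

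In 2-cell embryos, in which the embryo's own genome is first broadly transcribed, no single gene passed between VCD and PBS. Zscan4d, of that first wave of transcription, had 295 ± 15.2 FPKM (SD, n = 4) with PBS and 285 ± 73.3 (n = 4) with VCD, although 49.6% of its 50-base words occur in related genes, so its own level is uncertain. Dppa3 had 282 ± 46.98 and 320.1 ± 115 FPKM, Pou5f1 10.1 ± 3.18 and 10.8 ± 3.33, and Cdkn1a, a p53-induced inhibitor of the cell cycle, 7.07 ± 2.47 and 5.37 ± 2.32. Sod2 had 33.7 ± 1.33 and 30.9 ± 5.08 FPKM, and Hspa5 21.4 ± 2.91 and 23.7 ± 5.24. The oocyte transcripts Gdf9, Zp3 and Mos had 147 ± 13.2 and 156 ± 10.7, 29.2 ± 4.65 and 29.2 ± 3.25, and 1.48 ± 0.317 and 1.45 ± 0.660 FPKM. Nanog and Cdx2 were too low to be tested.

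The smallest p belonged to Rnu73b (ENSMUSG00000064390), a small nucleolar RNA of 71 bases on chromosome 3 from 86140618 to 86140688, inside the ribosomal protein gene Rps3a1 on the same strand. None of its 50-base words occur in annotated transcripts of another gene, but reads of unspliced host RNA could not be told from its own. It had 3.80 ± 1.58 FPKM with PBS and 0.187 ± 0.374 with VCD (log2 fold change −2.01, SE 0.26, adjusted p = 0.139), which corresponded to 18 reads and 1. It passed without VCD replicate 3 (adjusted p = 0.0475, but 0.0524 on the genes of the full set) and with array weights (0.0491), in a range of 0.0338 to 0.917. The following genes had an adjusted p of 0.850. Gipc1, a scaffold protein of receptor trafficking, had 0.430 ± 0.212 FPKM with PBS and 1.78 ± 0.427 with VCD (0.96, SE 0.17). mt-Atp6, a subunit of the mitochondrial ATP synthase, had 293 ± 22.2 and 169.6 ± 34.8 FPKM (−0.80, SE 0.15), and Rdh14, a retinol dehydrogenase, 9.35 ± 1.36 and 4.60 ± 1.18 (−0.90, SE 0.17). Rac1, a GTPase of the cytoskeleton, had 59.8 ± 8.46 and 37.9 ± 4.63 FPKM (−0.64, SE 0.13), Gpx6, a glutathione peroxidase, 13.8 ± 1.41 and 8.83 ± 0.724 (−0.59, SE 0.12), and H2-Q6, a class I histocompatibility gene, 1.86 ± 0.283 and 4.43 ± 1.29 (0.90, SE 0.19). Of their words, 99.5% for mt-Atp6, 50.3% for Rac1 and 35.0% for H2-Q6 occur in another gene, so these values are uncertain. Gm8940 (−1.06, SE 0.21), Gm24842 (−1.83, SE 0.37) and 4930564D02Rik (−0.85, SE 0.19, adjusted p = 0.883) were the remaining ones. Of 11369 genes tested with limma, 0 passed, 391 had an unadjusted p below 0.05 where 568.45 would by chance, and voom called 0, with 495 below 0.05. A mean of 5 FPKM or more in the higher group was found for 6039 genes. Of these, 5825 (96.5%) had a 95% confidence interval within a 2-fold change.

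Of 29 lists in 2-cell embryos, 2 passed. All 12 tested mitochondrially encoded genes had negative values, with a median of −0.28 (adjusted p = 2.34e-07; adjusted p = 0.841 with an estimated correlation). VCD replicate 3 ran the other way in their summed share, which at 6.82% of all FPKM lay above those of the PBS libraries (5.53% to 6.45%). The 7 members with most of their words in other genes had a median of −0.41, with an unadjusted p of 2.90e-07 (0.00901 with an estimated correlation). The other 5 had a median of −0.23, with an unadjusted p of 0.00196 (0.145 with an estimated correlation). mt-Atp6 passed when adjusted over the list alone and not over all genes; mt-Co3, a subunit of cytochrome c oxidase, had 8.77 ± 0.471 FPKM with PBS and 5.34 ± 2.70 with VCD. Of 42 ribosome biogenesis genes, 35 were positive and 7 negative, with a median of 0.11 (adjusted p = 0.0122; adjusted p = 0.841 with an estimated correlation), and no member passed in either adjustment. Nop16, a nucleolar protein, had 11.02 ± 1.80 and 14.9 ± 2.39 FPKM, and Ftsj3, which methylates ribosomal RNA, 5.62 ± 1.14 and 7.48 ± 0.671. In polarity and junctions, Rac1 passed when adjusted over the list alone. Autophagy and lysosome had the next smallest adjusted p (0.0769), with 21 of 26 members positive, and in 2 lists that did not pass the median, the mean and the test differed in sign. Ribosome biogenesis lost its call without PBS replicate 1 (adjusted p = 0.0687), without VCD replicate 4 (0.309) and with array weights (0.0949), in a range of 0.000428 to 0.841.

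In morulae, Gm25332, annotated as a small nuclear RNA, rose with VCD: it was listed at 0 in all 4 PBS libraries and had 4.29 ± 0.595 FPKM (SD, n = 4) with VCD (adjusted p = 0.000408). None of the fixed panel passed (adjusted p = 0.99997). Pou5f1 had 25.6 ± 6.08 FPKM with PBS and 29.8 ± 3.198 with VCD, Nanog, a factor of the inner cell mass, 23.1 ± 6.37 and 20.4 ± 6.29, and Cdx2, a factor of the outer trophectoderm, 3.68 ± 1.70 and 3.99 ± 2.62. Cdkn1a had 62.0 ± 10.1 and 76.4 ± 15.3 FPKM, Hspa5 68.8 ± 16.02 and 75.1 ± 15.0, and Sod2 74.9 ± 17.1 and 81.1 ± 20.5. Dppa3 had 256 ± 27.3 and 324 ± 93.3 FPKM, Zp3 31.1 ± 8.08 and 26.4 ± 3.75, and Gdf9 1.22 ± 0.557 and 2.04 ± 0.963. Mos and Zscan4d were too low to be tested.

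Gm25332 (ENSMUSG00000088663) is 105 bases long, lies on chromosome X from 92882451 to 92882555 and overlaps no other gene listed in the deposited tables. Its values corresponded to 0 reads with PBS and 29 with VCD, 6 to 8 in each library. In 2-cell embryos it had 7.67 ± 1.57 FPKM with PBS and 6.93 ± 5.83 with VCD. In oocytes it ranged from 9.33 to 11.3 FPKM with PBS and from 5.76 to 12.8 with VCD. Among genes that did not pass, Spp1, the secreted protein osteopontin, had 2.81 ± 1.29 FPKM with PBS and 0.315 ± 0.218 with VCD (log2 fold change −1.49, SE 0.26, adjusted p = 0.388). Khdc3, of the subcortical maternal complex, had 12.05 ± 4.13 and 30.5 ± 7.29 FPKM (1.30, SE 0.27, adjusted p = 0.649), and Hes1, a repressor induced by Notch signalling, 35.7 ± 12.97 and 84.1 ± 19.5 (1.26, SE 0.27, adjusted p = 0.764). Syap1 had 48.1 ± 9.81 and 93.8 ± 16.3 FPKM (0.95, SE 0.19, adjusted p = 0.598), and Gm13273 29.1 ± 5.96 and 8.05 ± 4.59 (−1.90, SE 0.38, adjusted p = 0.598). Gm42977 (1.15, SE 0.20), Gm17177 (−1.30, SE 0.23), Gm23504 (−2.07, SE 0.38) and Gm23910 (−1.65, SE 0.36) completed the 10. Khdc3 shares 34.1% of its words with Gm20509, and Gm42977 and Gm17177 share 49.5% and 35.1% with other genes, so their values are uncertain. Of 9959 genes tested with limma, 1 was higher and 0 were lower, 311 had an unadjusted p below 0.05 where 497.95 would by chance, and voom, which did not test Gm25332, called 0, with 376 below 0.05. A mean of 5 FPKM or more in the higher group was found for 5832 genes. Of these, 5051 (86.6%) had a 95% confidence interval within a 2-fold change. Gm25332 was not tested with a minimum of 10 FPKM or 10 reads in 4 libraries, with voom, nor without any 1 VCD library under the filter, and kept an adjusted p of 0.000199 to 0.0349 wherever it was tested.

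**Figure D2:**
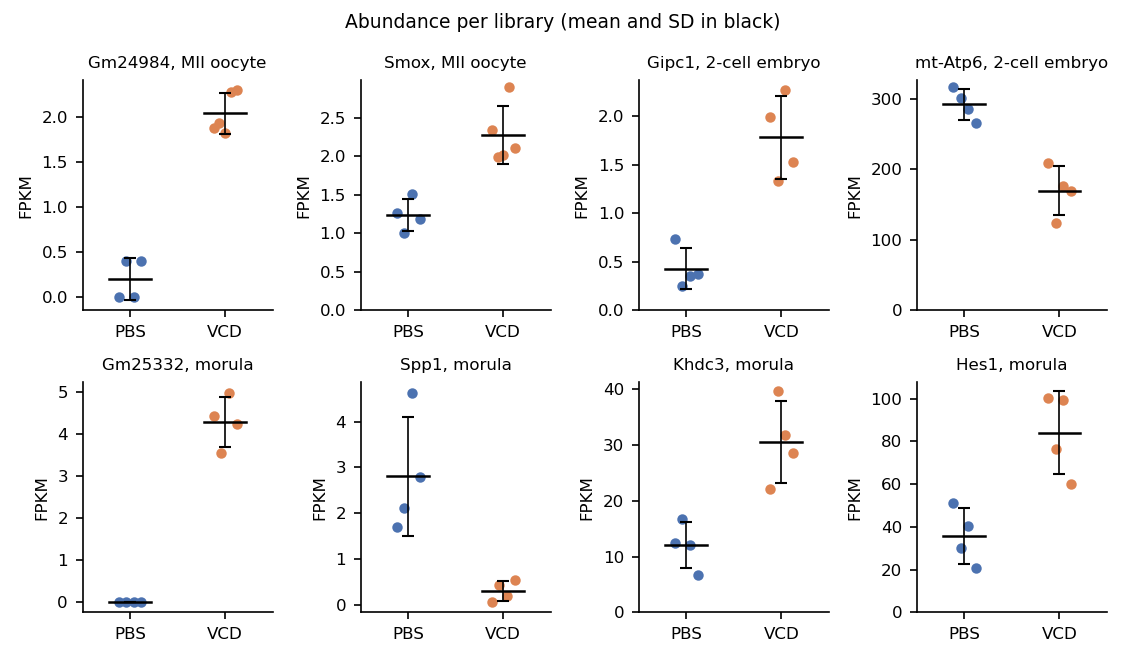
FPKM of 8 genes in each library with PBS and VCD: Gm24984 and Smox in oocytes, Gipc1 and mt-Atp6 in 2-cell embryos, and Gm25332, Spp1, Khdc3 and Hes1 in morulae; points are libraries, and black marks are the mean and SD. Gm24984 (0.200 to 2.04 FPKM) and Gm25332 (0 to 4.29 FPKM) passed the test, and the others did not.

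Of 29 lists in morulae, 4 passed, each higher with VCD. The mitochondrially encoded genes had 11 of 12 members positive, with a median of 0.17 (adjusted p = 0.000861; adjusted p = 0.855 with an estimated correlation), and 1 member, mt-Nd4l, passed when adjusted over the list alone and not over all genes. It had 1.60 ± 0.320 FPKM with PBS and 3.89 ± 1.47 with VCD, and mt-Co2 28.8 ± 5.13 and 43.5 ± 9.57, with 98.8% and 100% of their words in other genes. The 7 members with most of their words in other genes were all positive, with a median of 0.34. The other 5, of which 4 were positive, had a median of 0.12 and did not pass on their own, with an unadjusted p of 0.209. The summed share of FPKM in VCD replicates 2 and 4 (6.21% and 6.46%) was below that of at least 3 of the 4 PBS libraries (6.28% to 7.77%). Of 76 ribosomal protein genes, 57 were positive, with a median of 0.09 (adjusted p = 0.0158; adjusted p = 0.960 with an estimated correlation); Rps2 had 781 ± 256 and 1281 ± 306 FPKM. The maternal effect genes, which act in the early embryo from RNA or protein stored in the oocyte, had 20 of 25 members positive, with a median of 0.14 (adjusted p = 0.0286; adjusted p = 0.855 with an estimated correlation), and Khdc3 passed when adjusted over the list alone. Khdc3 reached at most 1.34 FPKM in oocyte libraries and 0.235 in 2-cell libraries. With 34.1% of its words in Gm20509 these low values are uncertain too. Whether its RNA in morulae was stored RNA cannot be told from them. Btg4 of the same list had 5.97 ± 0.334 and 4.43 ± 1.56 FPKM. DNA and histone modification had 33 of 45 members positive, with a median of 0.11 (adjusted p = 0.0286; adjusted p = 0.855 with an estimated correlation); Kdm5b, a histone demethylase, had 16.1 ± 1.31 and 20.0 ± 0.805 FPKM. In pluripotency and inner cell mass, Spp1 passed when adjusted over the list alone, and the list did not pass. The smallest adjusted p of the other lists was 0.144, and in 5 of them the median, the mean and the test differed in sign.

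Without VCD replicate 3 none of the 4 morula lists passed (mitochondrially encoded, adjusted p = 0.0916; ribosomal proteins, 0.5259; maternal effect, 0.358; DNA and histone modification, 0.309). Without PBS replicate 4 the mitochondrially encoded (0.0818) and ribosomal protein (0.707) lists did not pass. Maternal effect and DNA and histone modification did not pass without PBS replicate 1 (0.193 and 0.172), PBS replicate 3 (0.251 and 0.367) or VCD replicate 1 (0.0731 and 0.0760). Without VCD replicate 1 the test of ribosomal proteins reversed in direction and did not pass (adjusted p = 0.593). Over the alternatives of the 4 lists in the same order, the adjusted p ranged from 1.03e-05 to 0.978, 4.88e-10 to 0.991, 0.00518 to 0.978 and 0.00518 to 0.978.

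The VCD effect was then compared between morulae and 2-cell embryos. The mitochondrially encoded genes differed between the stages: all 12 had a more positive VCD effect in morulae, with a median difference of 0.43 (adjusted p = 3.55e-10; adjusted p = 0.260 with an estimated correlation). mt-Nd4l, a subunit of respiratory complex I, had 4.67 ± 0.952 FPKM with PBS and 2.85 ± 1.12 with VCD in 2-cell embryos, against 1.60 ± 0.320 and 3.89 ± 1.47 in morulae (n = 4 each). No member passed over all genes, and 4 passed when adjusted over the list alone. Most of the words of 7 members also occur in other annotated genes, between 51.1% for mt-Co1 and 100% for mt-Co2, so these members are uncertain. The other 5 (mt-Nd1, mt-Nd2, mt-Nd5, mt-Nd6 and mt-Cytb) had a median difference of 0.37, against 0.89 for those 7.

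**Figure D3:**
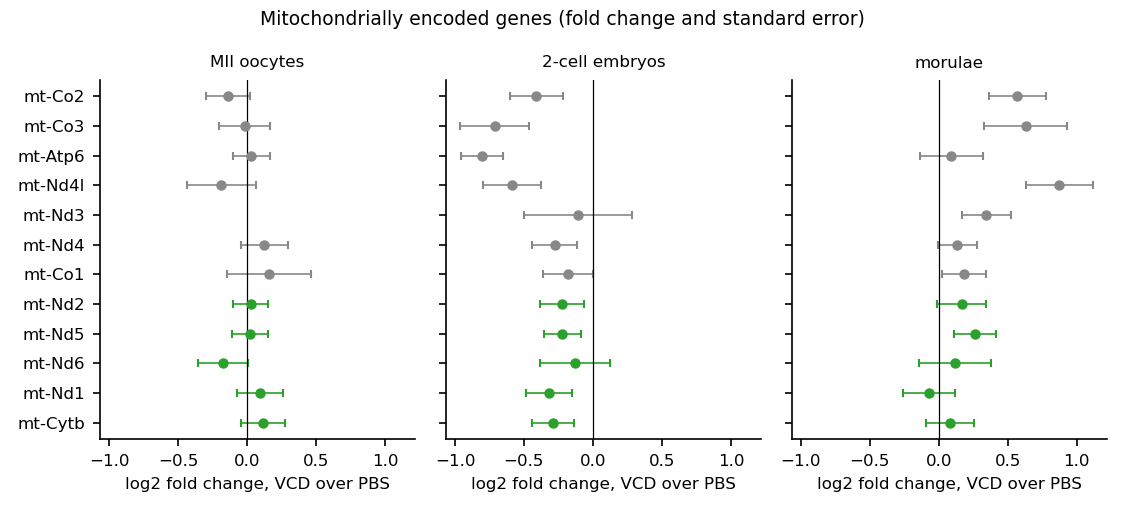
VCD effect (log2 fold change of FPKM + 1 with its SE) of each mitochondrially encoded gene in oocytes, 2-cell embryos and morulae; green marks the 5 members with under 10% of their 50-base words in another gene and grey the others. All 12 values lay below 0 in 2-cell embryos (median −0.28), and 11 of 12 above 0 in morulae (median 0.17).

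No single gene passed for the difference between stages. Thap11, a transcription factor of pluripotent cells, had 60.7 ± 5.32 FPKM with PBS and 43.5 ± 5.70 with VCD in 2-cell embryos, and 12.3 ± 1.22 and 20.97 ± 4.07 in morulae (difference of log2 fold changes 1.18, SE 0.21, adjusted p = 0.188). Gclm, of glutathione synthesis, had 3.19 ± 0.231 and 2.14 ± 0.419 FPKM, then 7.93 ± 1.05 and 13.2 ± 3.09 (1.07, SE 0.22, adjusted p = 0.429). Hes1 had 13.8 ± 5.81 and 6.50 ± 1.84 FPKM, then 35.7 ± 12.97 and 84.1 ± 19.5 (2.19, SE 0.44, adjusted p = 0.429). Rac1 had 59.8 ± 8.46 and 37.9 ± 4.63 FPKM, then 13.2 ± 5.44 and 26.2 ± 7.42 (1.65, SE 0.37, adjusted p = 0.542). Gm13273 (−2.77, SE 0.47) and Gm25332 (2.79, SE 0.48) had an adjusted p of 0.176, Khdc3 (1.42, SE 0.30) and Gm8940 (1.06, SE 0.23) 0.429, and Pcgf6 (0.75, SE 0.17) 0.542; Gm8940 was listed at 0 in all morula libraries. Of 14144 genes tested with limma, 0 passed, 502 had an unadjusted p below 0.05 where 707.2 would by chance, and voom called 0, with 746 below 0.05. A mean of 5 FPKM or more in the highest embryo group was found for 8457 genes, which could be low in the other stage. Of these, 6310 (74.6%) had a 95% confidence interval within a 2-fold difference. Of 30 lists, 1 passed. The next smallest adjusted p was 0.118, that of the Y-linked genes among them, with 1 of 5 members positive. In maternal effect, antioxidant defence, and polarity and junctions, 1 gene each passed when adjusted over the list alone, and in 6 lists the median, the mean and the test differed in sign. Gm25332 passed without 2-cell VCD replicate 1 (adjusted p = 0.000664) and with a pseudocount of 0.1 (0.000348), in a range of 0.000348 to 0.548, and Gm13273 without morula VCD replicate 4 (0.0475), in a range of 0.0475 to 0.537.

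Correlations of the VCD effects between stages were low and moved with single libraries. Across the 8030 genes tested in oocytes and 2-cell embryos, the log2 fold changes had a Pearson's r of 0.158 and a Spearman's rho of 0.172. These were 0.0832 and 0.101 for oocytes and morulae (5764 genes) and −0.0422 and 0.0278 for 2-cell embryos and morulae (7357 genes). The first r was 0.0868 without oocyte VCD replicate 4, 0.102 without 2-cell PBS replicate 4, 0.0550 without 2-cell VCD replicate 4 and 0.0293 with array weights. The second was 0.0130 without oocyte PBS replicate 4, 0.0279 without morula PBS replicate 3 and 0.0524 without morula VCD replicate 2. The third took both signs, from −0.123 without morula VCD replicate 4 to 0.0863 without morula PBS replicate 4, so no relation was shown. Genes are not independent replicates, and no p is given. With an unadjusted p below 0.05 and the same direction there were 9, 4 and 4 genes, where independent lists would share 2.996, 2.75 and 3.47. Called in both stages were 0 genes by limma in each pair.

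Many genes changed between the 2-cell stage and the morula in PBS embryos. Vnn1, which releases pantothenate from pantetheine, rose from 0.141 ± 0.118 FPKM (SD, n = 4) to 289 ± 48.7 (log2 fold change 7.98, SE 0.16, n = 4), Isyna1, which makes inositol phosphate, from 4.38 ± 1.01 to 1019 ± 92.4 (7.58, SE 0.15), and Bhmt, which methylates homocysteine, from 0.341 ± 0.173 to 204 ± 43.3 (7.24, SE 0.18). Fbp2, of gluconeogenesis, rose from 1.83 ± 0.795 to 346 ± 29.5 FPKM (6.98, SE 0.20) and Timd2 from 3.56 ± 0.333 to 572 ± 133 (6.95, SE 0.17). Rfpl4 fell from 3818 ± 360.0 to 0.772 ± 0.398 FPKM (−11.09, SE 0.16), Bcl2l10, a member of the Bcl-2 family abundant in oocytes, from 9403 ± 423 to 3.91 ± 2.53 (−11.07, SE 0.34), and Zbed3, of the subcortical maternal complex, from 14902 ± 2450.5 to 6.85 ± 1.54 (−10.90, SE 0.18). Tcl1b1 (−10.17, SE 0.51) and Tcl1 (−9.74, SE 0.30) followed. Of the fixed panel, Nanog (4.37, SE 0.20), Cdkn1a (2.997, SE 0.22), Cdx2 (2.03, SE 0.24), Hspa5 (1.62, SE 0.19), Pou5f1 (1.28, SE 0.25) and Sod2 (1.10, SE 0.17) rose, and Zscan4d (−7.52, SE 0.28), Gdf9 (−6.10, SE 0.19) and Mos (−0.995, SE 0.18) fell. Zp3 (0.07, SE 0.19, adjusted p = 0.734) and Dppa3 (−0.13, SE 0.14, adjusted p = 0.393) did not pass. Of 12517 genes tested with limma, 5343 were higher and 5635 lower in morulae, and the groups did not overlap for 10441 (83.4%), against 2.86% by chance. Of the calls 48.7% were higher. Without any 1 of the 2-cell PBS libraries this share was 64.7% to 65.3%, and without any 1 of the morula PBS libraries 40.5% to 40.8%, since the filter then removes genes present only in the smaller group; on the genes of the full set it was 48.3% to 48.7%. With rescaling by the median of ratios the median of all genes moved from −0.08 to −0.44, 4727 genes were higher and 6248 lower, and Dppa3 passed (−0.49, adjusted p = 0.0107, in a range of 0.0107 to 0.824). With the number of detected genes as a covariate, which differs between the stages itself, 3630 genes passed. Under it Mos, Hspa5, Cdx2, Pou5f1, Sod2 and Tcl1b1 did not pass, with the highest adjusted p of their ranges (8.33e-05 to 0.138, 1.70e-06 to 0.0621, 2.22e-06 to 0.301, 2.72e-04 to 0.0725, 6.33e-06 to 0.226 and 5.19e-10 to 0.0538).

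Of 29 lists, 10 were higher and 3 lower in morulae. With an estimated correlation ribosome biogenesis alone passed (adjusted p = 0.0232); the adjusted p with an estimated correlation of the other 12 lay between 0.0854 for autophagy and lysosome and 0.336 for p53 targets. All 75 ribosomal protein genes rose (median 3.95), Rpl6 from 15.8 ± 1.83 to 993 ± 155 FPKM, as did all 44 ribosome biogenesis genes (median 2.62), Ddx21 from 3.50 ± 0.452 to 94.6 ± 11.98. Of the nuclear oxidative phosphorylation genes 69 of 75 rose and 1 fell (median 2.39), with Ndufa9 at 3.96 ± 0.660 and 162 ± 13.1 FPKM, and of the proteasome genes 31 of 32 rose (median 3.24), with Psmd14 at 9.85 ± 0.878 and 383 ± 24.0. Heat shock (18 of 22 rose, 3 fell, median 2.59), autophagy and lysosome (26 of 31 rose, 5 fell, median 2.49) and lipid droplet and fatty acid oxidation (18 of 21 rose, 3 fell, median 1.75) were higher too, with Hspa8 at 13.7 ± 1.195 and 938 ± 118, Lamp1 at 12.3 ± 0.673 and 221 ± 29.1, and Acadl at 2.95 ± 0.477 and 319.8 ± 16.6 FPKM. Trophectoderm genes (20 of 27 rose, 2 fell, median 2.02) included Cldn4, a tight junction protein, at 0.299 ± 0.125 and 153 ± 22.0 FPKM. Pluripotency and inner cell mass genes (20 of 24 rose, 3 fell, median 1.97) included Tdgf1 at 0.271 ± 0.118 and 68.9 ± 22.2, and p53 targets (18 of 27 rose, 4 fell, median 1.16) Phlda3 at 0.0297 ± 0.0593 and 20.9 ± 6.14. Oocyte identity genes were lower (27 of 28 fell, median −6.29), with Bmp15 at 1562 ± 202 and 0.908 ± 0.0739 FPKM. Maternal effect genes were lower as well (22 of 30 fell, 5 rose, median −3.32), as were 2-cell zygotic activation genes (34 of 38 fell, 3 rose, median −4.18). Of the latter, 22 without the near-identical Zscan4, Tdpoz and Usp17l families had 19 that fell and 2 that rose.

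The adjusted p of the 13 lists lay between 2.08e-17 for ribosomal proteins and 0.00892 for p53 targets. Counts of members adjusted over the list alone equalled those over all genes, except DNA repair (10 against 11 lower) and unfolded protein response (15 against 16 higher). The 16 lists that did not pass had an adjusted p from 0.0837 for apoptosis to 0.992. They were meiotic cell cycle and spindle, maternal RNA decay and translation control, mitochondrially encoded, glycolysis, antioxidant defence, DNA repair, apoptosis, unfolded protein response, DNA and histone modification, primitive endoderm, polarity and junctions, mitotic cell cycle, cholesterol synthesis, xenobiotic response, imprinted genes, and cumulus and granulosa cells. Cumulus and granulosa cell markers had 4 of 7 higher and 2 lower in morulae (adjusted p = 0.306), and for VCD an adjusted p of 0.978 in 2-cell embryos and 0.444 in morulae. Sperm, blood cell and Y-linked lists had fewer than 5 tested members. The median, the mean and the test differed in sign in 3 lists that did not pass. The p53 target list lost its call with a minimum of 10 FPKM (adjusted p = 0.146) and without any 1 of the 2-cell PBS libraries under the filter (0.192 to 0.245), in a range of 1.72e-05 to 0.336. On the genes of the full set it passed without each of these libraries. The lipid list lost it with a minimum of 10 FPKM (0.0514), in a range of 8.17e-08 to 0.103.

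**Figure D4:**
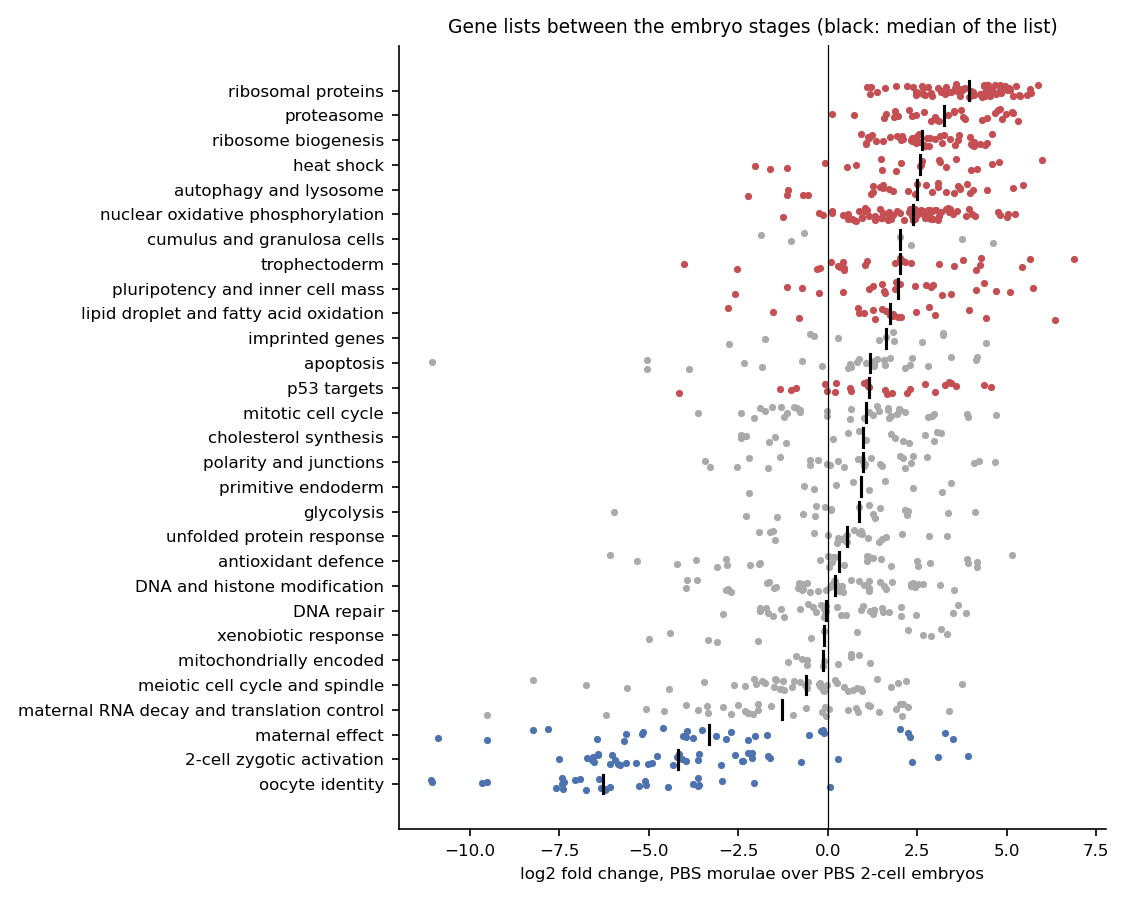
Log2 fold change (FPKM + 1) of every tested member of 29 gene lists between PBS 2-cell embryos and PBS morulae; red points passed as higher, blue as lower, grey did not pass, and black marks the list median. Medians ran from −6.29 for oocyte identity to 3.95 for ribosomal proteins.

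VCD embryos repeated the change between the stages. Of 10476 genes that changed in PBS embryos and were tested in both, 9875 changed the same way in VCD embryos and 0 the opposite way by limma. The log2 fold changes of 11916 genes had a Pearson's r of 0.993 and a Spearman's rho of 0.991 across genes, which are not independent replicates.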

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

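The tests of other splits of the libraries, of the mitochondrially encoded genes and of shared words were chosen after the results were seen; those of counting noise, of single VCD libraries and of the number of detected genes for the distances were written before their results.

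The larger distances among VCD libraries were noticed in the data and tested on the same data, so a greater spread with VCD is a hypothesis. The ratio of the mean distance with VCD to that with PBS was 1.94 in oocytes (two-sided exact permutation p = 0.00794, the smallest that 126 regroupings can give; adjusted p = 0.0238), 1.43 in 2-cell embryos (exact p = 0.114) and 1.30 in morulae (exact p = 0.229). Of 617400 regroupings within the 3 stages, 185 had a summed log2 ratio as far from 0 as the real 1.85 (permutation p = 3.00e-04). The highest other was 2.16, and this p argues against chance. Genes at 20 FPKM or more gave a permutation p of 4.16e-04, against counting noise of low genes. Sets without 1 VCD library gave a permutation p of 7.77e-05 to 0.00186, against a single library as the source of the sum. These sets still add up the 3 stages, so they cannot exclude a single library within a stage. The sum fell to 1.49 without 2-cell VCD replicate 4 and to 1.62 without morula VCD replicate 2. Once the trend of each gene with the number of detected genes was removed, the permutation p was 0.701. By the test as written this would point to that number as the source. A control added afterwards shuffled the numbers within each agent, which kept their wider spread among VCD libraries. The sum came as near to 0 in 25 of 100 shuffles, with a median of 0.544 against 0.243 for the real numbers. The test thus cannot tell the real numbers from shuffled ones of the same wider spread, and decides nothing about this source. A quality of the RNA or cDNA that varies among VCD libraries and a biological difference between the cells may both remain, and neither was tested.

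The calls of Gm24984 in oocytes and Gm25332 in morulae rested on few reads. Exact binomial tests of the summed reads, adjusted over all listed genes with a read, gave 4.95e-04 and 1.58e-09, which argues against counting noise alone. That test took no account of the spread between libraries, and 4938 of 24142 and 10216 of 25221 genes passed it. Of 100 splits of the oocyte libraries 6 called as many genes as the real 1 (highest other 4), and of 35 splits of the morula libraries 4 did (highest other 1), so chance could not be excluded for either count. Whether the reads at these short genes came from the annotated small RNAs themselves was not tested. An effect of VCD on these RNAs may still be present and stays open.

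In limma's camera, the mitochondrially encoded genes differed in their VCD effect between morulae and 2-cell embryos by a median of 0.43 (adjusted p = 3.55e-10). Of 100 splits 1, the real one, gave an unadjusted value as small (1.18e-11; lowest other 2.74e-06); in 2-cell embryos this was 1 of 35 (8.06e-09; lowest other 5.99e-08) and in morulae 2 of 35 (2.97e-05; lowest other 1.76e-07), for a list picked from 30 after its result was seen, so the splits exclude less than they seem to. The number of detected genes as a covariate left an adjusted p of 1.61e-10 in camera at the preset correlation, so it did not weaken that value. The covariate was not run with an estimated correlation, so that number stays open as a source. Members that vary together may weigh as few genes (adjusted p = 0.260 with an estimated correlation), and nuclear copies also stay open: the 7 members with most words shared gave an unadjusted p of 7.82e-11 (0.00101 with an estimated correlation), and the 5 with few gave 0.00207, which met the bound written against that explanation, but 0.119 with an estimated correlation, a criterion added after that result was seen. A change of mitochondrial transcripts with VCD that differs by stage stays open as a hypothesis.

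Among 164 groups of values, 11 (6.71%) held a library far from the others, where chance gives 5%. In 2-cell embryos with VCD, replicate 4 stood apart in Gm24842 (1.04 FPKM, the others at 0), Rac1 (44.9 FPKM, next 36.1) and Dppa3 (491 FPKM, next 280.4). In 2-cell embryos with PBS, replicate 3 was highest in Gm8940 (2.81 FPKM, next 1.74). In morulae with PBS, replicate 3 was highest in the mitochondrial share (7.77%, next 6.53%), replicate 1 lowest in Gm23504 (1.003 FPKM, next 4.89) and replicate 2 highest in Zp3 (43.1 FPKM, next 28.03). In morulae with VCD, replicate 4 was lowest in Sod2 (50.8 FPKM, next 86.1), replicate 3 highest in Hspa5 (97.4 FPKM, next 68.8) and replicate 1 lowest in Pou5f1 (24.96 FPKM, next 31.2). In oocytes with PBS, replicate 1 had a Y-linked sum of 0.00380 FPKM, the others 0.

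In both stages of the embryo the groups of 4 genes did not overlap, in opposite directions. They were looked for among the named genes, many of them picked for a small p, so this pattern was partly built in. Over all tested genes the groups did not overlap for 2.16% in 2-cell embryos and 2.04% in morulae, against 2.86% by chance. The differences between the stages were 1.65 for Rac1 (adjusted p = 0.542), −2.77 for Gm13273 (adjusted p = 0.176), 1.18 for Thap11 (adjusted p = 0.188) and 1.07 for Gclm (adjusted p = 0.429), and none passed.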

How the results depend on the processing

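The fits on recovered reads, with array weights and on the genes of the full set were chosen after seeing the data. Alternatives left 120 counts of genes within 1.5 times, with 10 higher and 15 lower, and 92 counts of lists, with 31 higher and 32 lower; 59 correlations moved by less than their spread and 19 by more. Of the named genes 2694 values stayed on their side of the threshold, 10 gained and 9 lost the call. Those of called genes kept their direction, while some of genes without a call changed sign, such as the difference between stages of Nanog (−0.35 to 0.32). Where no construction is given below, the cause was not tested.

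In oocytes 0 genes passed with no filter, with minimums of 10 FPKM or 10 reads and with voom (Gm24984 not tested in the last 3), and with a pseudocount of 0.1; leaving out each library gave 1 throughout. In 2-cell embryos 1 passed with array weights and 0 to 1 without a library (1 without VCD replicate 3). In morulae 0 passed with 10 FPKM, 10 reads and voom, and 0 to 1 without a library, since Gm25332 then misses the filter; on the full set 2 passed without PBS replicate 1, adding Gm23504 (adjusted p = 0.00795, range 0.00795 to 0.9999). For the difference between stages 2 passed with no filter (4930573H18Rik and Gm26415), 1 with a pseudocount of 0.1 and 0 to 2 without a library, also on the full set (2 without 2-cell VCD replicate 1, 1 without morula VCD replicate 4). Between the stages in PBS 4832 passed with 10 FPKM, where fewer genes were tested, and 3630 with detected genes as a covariate, which differ by stage themselves; without a library 7970 to 9585 passed, and 10776 to 11045 on the full set.

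Replicate numbers did not pair the oocyte libraries, and paired those of the embryos only in part. The r of the deviations of same-numbered libraries exceeded 0.1 in 0 of 4 pairs of oocytes, 1 of 4 of 2-cell embryos and 2 of 4 of morulae. In the same order 0, 1 and 2 correlated best with their own number. Morula numbers 1 and 4 had an r of 0.326 and 0.378, against at most 0.0101 and 0.00375 with another number. A shared source of these libraries was not excluded. With the numbers as a block 0, 1 and 1 genes passed in the 3 stages: Rnu73b in 2-cell embryos (adjusted p = 0.0338, range 0.0338 to 0.917) and Gm25332 in morulae, and not Gm24984 in oocytes (adjusted p = 0.118, range 0.00230 to 0.394).

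Lists called in oocytes were 0 with no filter, 10 FPKM, voom, an estimated correlation and fry, 0 to 1 without a library, and 0 on the full set without PBS replicates 1, 3 or 4 or VCD replicates 2 or 4. In 2-cell embryos they were 6 with array weights, 0 with an estimated correlation and fry, 1 to 6 without a library, and on the full set 1 without PBS replicate 1, 4 without PBS replicate 3 or VCD replicate 1, and 6 without VCD replicate 3. In morulae they were 2 with 10 FPKM and voom, 0 with an estimated correlation and fry, 0 to 5 without a library, and on the full set 2 without PBS replicates 1 or 4 or VCD replicate 1 and 0 without VCD replicate 3. For the difference between stages they were 2 with 10 FPKM and voom, 3 with array weights, 0 with an estimated correlation and fry, and 1 to 3 without a library; on the full set 3 without 2-cell PBS replicate 4, 2-cell VCD replicates 1 or 4 or morula VCD replicate 4, and 2 without 2-cell PBS replicate 3, morula PBS replicates 1, 3 or 4 or morula VCD replicates 1, 2 or 3. Between the stages in PBS they were 1 with an estimated correlation and 27 with fry. DNA and histone modification lost its call in oocytes with no filter (adjusted p = 0.0812), 10 FPKM (0.511) and voom (0.0502), and in morulae with no filter (0.0707), 10 FPKM (0.262) and voom (0.0618). In morulae maternal effect lost it with 10 FPKM (0.216), voom (0.0543) and on the full set without VCD replicate 4 (0.0514), and ribosomal proteins with voom (0.0543). Over all alternatives these 4 ranged from 0.00321 to 0.996, 0.00518 to 0.978, 0.00518 to 0.978 and 4.88e-10 to 0.991. The mean of the ribosomal protein genes in morulae was 0.00479 to 0.263 without a library; the lowest, without VCD replicate 1 in both forms, had a median of −0.02 and the test reversed.

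The correlation of oocytes and 2-cell embryos was 0.0812 with no filter, 0.199 with 10 FPKM, 0.0797 with voom, 0.0293 with array weights and 0.0550 to 0.219 without a library. That of oocytes and morulae was 0.0548 with no filter and 0.0130 to 0.111 without a library. That of 2-cell embryos and morulae was −0.118 with 10 FPKM, 0.0249 with voom and −0.123 to 0.0863 without a library. Without 1 library, 3 library measures reached an unadjusted exact p of 0.0286, the smallest these group sizes allow; it was not adjusted over the measures or the libraries left out: the share of the 10 most abundant genes in oocytes without VCD replicate 3 (−0.662, range −0.662 to −0.253), the mitochondrial share in 2-cell embryos without VCD replicate 3 (−1.36, range −1.36 to −0.457) and the implied depth of morulae without PBS replicate 2 (−3.26, range −3.26 to −2.01). Apart from voom on the recovered reads, fits made for counts, and comparisons of count normalizations, were not run, since the values were FPKM.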

Other observations

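The tests of other splits were chosen after the results were seen. In oocytes, many abundant transcripts varied more among the 5 VCD libraries than among the 4 PBS libraries. The median SD of log2 values was 0.18 with PBS and 0.44 with VCD for ribosomal proteins (27 of 30 members more variable with VCD), 0.19 and 0.40 for nuclear oxidative phosphorylation (39 of 43), 0.13 and 0.27 for oocyte identity (25 of 28), and 0.13 and 0.26 for maternal effect (21 of 28). For p53 targets it was 0.17 and 0.15 (10 of 18). Dppa3 ranged from 69.8 to 84.4 FPKM with PBS and from 54.3 to 200.2 with VCD, Mos from 236 to 278 and from 145 to 384, Hspa5 from 41.4 to 52.3 and from 24.9 to 70.8, and Zp2, a protein of the egg coat, from 187 to 548 and from 76.9 to 914. Zp2 was chosen after its values were seen. Over all tested genes, 75.1% were more variable with VCD in oocytes, 64.8% in 2-cell embryos and 60.9% in morulae.

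Transcripts of the sex chromosomes, also chosen after their values were seen, were present in all 8 morula libraries above 1 FPKM: Xist, the RNA that silences an X chromosome, at 2.56 to 14.6 FPKM, and the Y-linked Ddx3y and Eif2s3y at 1.18 to 8.91 and 1.80 to 9.52. In 2-cell embryos Xist lay between 0.00993 and 0.1196 FPKM, and Ddx3y and Eif2s3y passed 1 FPKM in 3 and 2 of 8 libraries.

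Other splits of the same libraries gave as many called genes as the real grouping in 35 of 35 splits of the 2-cell libraries (real 0, highest other 2) and in 100 of 100 for the difference between stages (real 0, highest other 4). With a real count of 0 every split gives as many, so these counts decide nothing. For called lists, 73 of 100 splits did so in oocytes (real 1, highest other 6), 29 of 35 in 2-cell embryos (real 2, highest other 7), 12 of 35 in morulae (real 4, highest other 8) and 95 of 100 for the difference between stages (real 1, highest other 13), so chance could not be excluded for these. For PBS morulae against PBS 2-cell embryos, 1 of 35 splits, the real one, called 10978 genes (highest other 0). Each other split mixes the stages in both groups, which widens their spread. Few calls were bound to follow there, so the count alone cannot exclude chance. The real groups did not overlap for 83.4% of the tested genes, against 2.86% by chance. The 13 called lists of that comparison were matched in 14 of 35 splits (highest other 16). A split of 3 morulae and 1 2-cell library against the reverse keeps part of the difference between stages, so this count decides nothing about chance.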
